A study of Gallus gallus with 24 samples.

How the data were processed

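Gene expression was measured with 24 Agilent 1-colour arrays, each hybridised with Cy3-labelled RNA of 1 sample. The samples were liver and breast muscle of chickens in 4 groups, with 3 arrays per group and tissue. Per the labels, PHF was given for 42 days, RNA was extracted with a kit for lipid-rich tissue, and 600 ng of total RNA entered the labelling. The array titles name the PHF group KP while the treatment field names it PHF, and the treatment field was followed. The labels do not state that the arrays of a group came from separate birds, so p-values measure the spread between samples and not that between birds. The diets of the control groups and the meaning of CCL were not given in the sources used here.

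Per the file headers, each array was read with Agilent Feature Extraction 11.5.1.1 under the protocol GE1_1105_Oct12, for a design annotated on galGal3:v2.1:May2006. The deposited scanner values are an intensity on a linear scale, background-subtracted and spatially detrended within the array and not scaled between arrays. The deposited series-wide values are log2 values of 28073 gene names, in 1 column per array. Its scale and centring were found by setting each column against the scanner values of its array. For names with 1 probe the column equalled the log2 of the processed signal minus a constant of the array, and the 75th percentiles of the columns lay between -0.00214 and 0.00536. The column medians for replicates 1 to 3 in liver were -2.92, -2.87 and -2.92 in the normal control, -2.86, -2.82 and -2.79 in the negative control, -2.83, -2.84 and -2.89 in PHF and -2.87, -2.74 and -2.81 in CCL. In muscle they were -2.87, -2.93 and -2.88, then -2.64, -2.73 and -2.79, then -2.69, -2.71 and -2.81, and -2.87, -2.81 and -2.93, in that order of groups. How the authors combined several probes of a gene stays unknown. Of its names, 28063 were found on the array.

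The processed signal was averaged over spots of a probe after control spots and spots with outlier marks were left out, saturated spots being kept. It was scaled by subtracting the array's 75th percentile from the log2 value. Of 43154 probes, 25121 had a gene symbol, taken from the names in the scanner files or, for accessions, from a reference table of accessions and symbols, and 11570 symbols were distinct. Gene names are those of the array's design and can be old. A gene was represented by the probe with the highest mean over the arrays of the fit, and probes without a symbol were tested on their own. A probe was kept where it lay well above background on all 3 arrays of at least 1 group. This left 22151 features in liver (9880 with a symbol), 20836 in muscle (9522) and 23333 over both tissues (10292).

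Groups were compared with limma 3.58.1 in R 4.3.3, with a mean per group over the 12 arrays of a tissue, a 2-sided moderated test and a Benjamini-Hochberg adjusted p under 0.05. The 6 pairs of groups were compared in each tissue. The difference between tissues of the PHF change against the negative control was a contrast over all 24 arrays. The tables were read with the R packages data.table, version 1.17.8, and jsonlite 2.0.0, statmod 1.5.0 served random blocks, and the plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Where every array of a group lay below background for a gene, a bound was given in place of a fold.

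Gene lists of pathways, complexes and cell types (35 in all, from general knowledge) were tested with camera at a preset correlation of 0.01 and again with an estimated one, for lists with at least 5 measured members. The adjusted p of a list is over the lists of 1 comparison. Members past the threshold were counted over all genes and adjusted over the list alone. Lists, the tests of the 13 comparisons, the rule for naming genes and all but 4 of the alternatives were fixed before the data were examined, and the tests of explanations were chosen after. The rule took genes with an informative symbol, an adjusted p under 0.05 and no overlap between the arrays of the groups compared. From these it took the 10 largest changes in each direction for PHF against the negative control, and 8 for the negative control against the normal control and CCL against the negative control. For the other comparisons and the difference between tissues it took 4. Where none passed, it took the 4 smallest p in each direction. It added the 4 members with the smallest p of each called list, 2 of each other list with a member past the threshold, and CHDH, BHMT, PEMT, CHKA, PCYT1A and MAT1A in comparisons with the negative control.

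Slide was tested by setting differences between CCL arrays of different slides against differences between the groups on those slides, with an exact permutation of the CCL arrays. Scan days did not divide the arrays of a tissue except for muscle CCL 3, which was scanned apart.

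The fit was tested on simulated data with the spread and the number of arrays of each tissue, for PHF against the negative control. With no gene changed it called 0 of 22123 features in liver and 0 of 20726 in muscle by limma. With 200 features changed it found 3, 28, 38 and 35 of 50 each at log2 changes of 0.5, 1, 1.5 and 2 in liver, and 6 of 21923 unchanged ones. In muscle it found 1, 22, 37 and 46 of 50, and 6 of 20526 unchanged ones. With slide as a fixed block it found 0, 0, 1 and 7 of 50 in liver, and 0, 0, 0 and 4 in muscle. Where only slide shifts were simulated, the fit without a slide term called 187 features in liver and 235 in muscle, and the fit with it called 0 in both.

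Alternatives covered background correction (normexp with an offset of 50), quantile normalization, the percentile taken over detected probes, the filter on dim probes, the treatment of several probes of a gene and outlier spots. They also covered slide and replicate number as blocks, the arrays in the fit, a trended and robust prior, array weights, the deposited table of log2 values, a further 2-fold threshold and leaving out each array. Probes not matched to a symbol were reported under their own name only where few features passed.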

Results

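Gene expression was measured in liver and breast muscle of chickens that belonged to 4 groups: a normal control, a negative control, birds given a polyherbal feed supplement (PHF) and a group labelled CCL. The labels give 42 days of supplementation, expand neither CCL nor the diets of the controls, and put 3 arrays in each group of each tissue, 24 in all. Each array carried 1 sample labelled with Cy3 on a chicken Agilent design of 43154 distinct probes. Between 67.9% and 79.4% of these probes lay well above background on an array, and the 75th percentile of the processed signal ran from 456 to 1042. The tissue labels matched the marker genes: the median of 29 hepatocyte genes lay between 6.92 and 7.47 (log2 over each array's 75th percentile) on the liver arrays. It lay between -5.57 and -2.84 on the muscle arrays. The median of 25 skeletal muscle genes ran from 4.42 to 4.97 in muscle and from -5.69 to -4.14 in liver.

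In each tissue the 3 arrays of the normal control, of the negative control and of PHF each filled 1 slide of their own, and the 3 CCL arrays were spread over those 3 slides. Each liver CCL array correlated best with an array of its own slide. The difference between CCL arrays of different slides correlated over genes with the difference between the groups on those slides (mean r = 0.399). That was the highest of the 6 possible orders of the CCL arrays, the next being 0.123, with an exact one-sided permutation p = 0.167, the smallest that 6 orders allow. In breast muscle the mean r was 0.0592 (exact one-sided permutation p = 0.5). For this reason differences are given both without a slide term and with slide as a block, in which case each group is set against the CCL arrays of its own slide. For CCL against another group the blocked value is the difference within the slide they share. For gene lists, "blocked" marks the median with slide as a block, and the adjusted p is camera's, first with the preset correlation and then, after "or", with an estimated correlation, by which 0 calls held in any comparison. Values in parentheses are log2 changes ± the standard error of limma's fit over the 12 arrays of a tissue, with n = 3 arrays per group, and every blocked value rests on 1 CCL array per slide. Where no array of a group lay well above background for a gene, the difference is a lower bound ("at least N-fold"), the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the probe's signal and the lowest signal well above background. Log2 values of such genes, blocked ones included, are fitted ones and not folds.

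**Figure D1:**
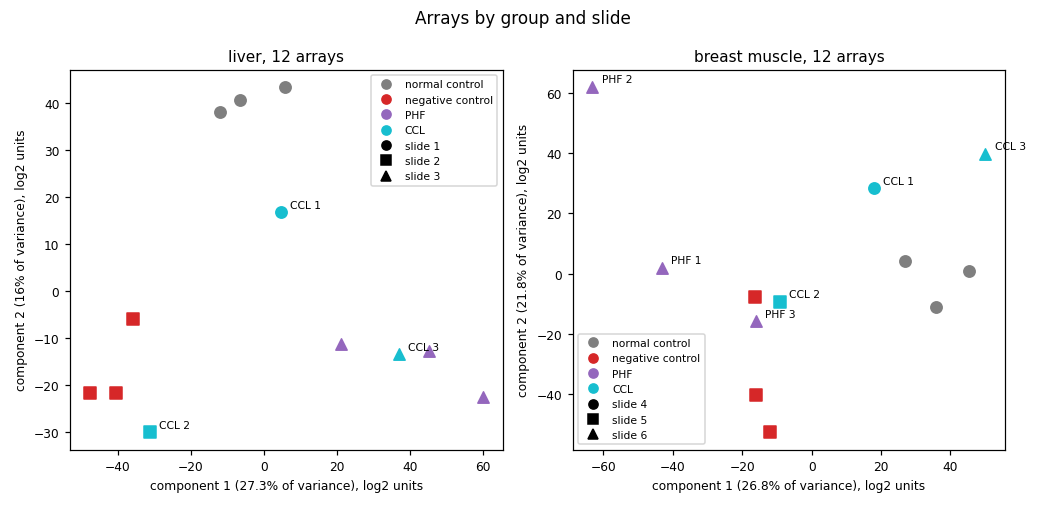
Position of the 12 arrays of liver (left) and of breast muscle (right) on principal components 1 and 2 of the log2 values, with the share of variance on the axes; marker shapes stand for the slide and colours for the group. Each liver CCL array lay nearest to the group of its own slide, and muscle PHF 2 lay apart from the other arrays.

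The liver of the negative control was set against that of the normal control to ask how the control groups differed from each other. ALDH1L2, a mitochondrial folate enzyme, was higher in the negative control (3.40 ± 0.44), as were CDKN1A, an inhibitor of cyclin-dependent kinases (2.63 ± 0.26), and VWF, the clotting glycoprotein of endothelial cells (3.17 ± 0.57). The membrane scaffold MPP2 (2.21 ± 0.36), HEMGN of blood-forming cells (1.99 ± 0.27), the mitochondrial chaperone HSPA9 (0.94 ± 0.13) and the branched-chain aminotransferase BCAT1 (0.78 ± 0.14) were also higher. PDE9A, a cyclic GMP phosphodiesterase, SH3BP2, an adaptor of immune signalling, and SMPX, a small muscle protein, were at least 1.38-fold, 1.45-fold and 1.35-fold higher. PIGR, the receptor that carries immunoglobulin A into bile (-2.30 ± 0.38), and AvBD13, an avian beta-defensin (-1.62 ± 0.21), were lower. The galanin receptor GALR1L (-1.04 ± 0.16) and the transcription factor NFIX (-0.98 ± 0.17) were lower as well. The adjusted p of these 14 genes ran from 0.0301 to 0.0499.

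As a list, ribosomal proteins stood higher than other genes (median 0.16, blocked 0.30, adjusted p = 0.000115, or 0.918 with an estimated correlation), although 0 of 67 members passed by limma; RPL37 lay at 0.53 ± 0.13 and RPS24 at 0.49 ± 0.12. Erythroid genes also stood higher (median 0.36, blocked 0.57, adjusted p = 0.0314 or 0.918). Of 19 measured, 1 rose (HEMGN) and 18 did not pass, 4 rose adjusted over the list alone, and the beta-globin HBBR lay at 2.12 ± 0.56. The interferon response stood lower (median -0.26, blocked -0.30, adjusted p = 0.00262 or 0.918) with 0 of 33 past the threshold, TAP2, a peptide transporter of antigen presentation, at -0.55 ± 0.16 and PARP9 at -0.61 ± 0.26. Plasma proteins (median -0.16, blocked -0.21, adjusted p = 0.00463 or 0.918) and hepatocyte genes (median -0.075, blocked -0.14, adjusted p = 0.0483 or 0.918) stood lower too, the plasma protein ITIH2 lying at -0.67 ± 0.14. Heat shock proteins stood lower as a list (median -0.21, blocked -0.17, adjusted p = 0.0321 or 0.918) although HSPA9 rose, and the co-chaperone DNAJA1 lay at -0.51 ± 0.12. The list of growth hormone, IGF and thyroid genes stood lower (median -0.14, blocked -0.12, adjusted p = 0.0483 or 0.918), with the iodothyronine deiodinase DIO1 at -0.57 ± 0.12. Of these 7 list calls 2 held with slide as a block. Of the genes of choline use, CHDH (-0.26 ± 0.12), BHMT (0.24 ± 0.31), PEMT (-0.48 ± 0.14), PCYT1A (0.059 ± 0.12) and MAT1A (0.015 ± 0.15) did not pass, with adjusted p from 0.112 to 0.969, and CHKA was not measured. In all, 109 of 22151 genes and unnamed probes passed, 88 higher and 21 lower in the negative control. With slide as a block none passed by limma (1091 at an unadjusted p under 0.05). In that fit ALDH1L2 lay at 2.90 ± 0.85, CDKN1A at 2.16 ± 0.54, PIGR at -2.21 ± 0.83, VWF at 0.37 ± 0.29 and SH3BP2 at 0.46 ± 0.31. GALR1L reversed with normexp correction but stayed below the median gene, and NFIX reversed in the deposited table. Leaving out 1 array gave 0 to 20 genes.

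The comparison of PHF with the negative control asks what differed in liver with the supplement, and it passed the most genes of the 13 comparisons (2002 of 22151, 1054 higher and 948 lower with PHF). More were lower than higher in 9 of 16 other settings, arrays left out aside, among them normexp correction (340 higher and 501 lower) and slide as a random block (443 and 498). The largest falls included the glycine transporter SLC6A9 (-3.96 ± 0.53), asparagine synthetase ASNS (-3.54 ± 0.40) and ALDH1L2 (-3.36 ± 0.44, 10.3-fold lower, past the threshold with all 4 of its probes). The glutamate transporter SLC1A6 was at least 4.83-fold lower, the alpha-tubulin-like TUBAL3 at least 3.08-fold and SH3BP2 at least 1.64-fold. The uridine phosphorylase UPP2 (-2.99 ± 0.80), PPM1K, the phosphatase that activates branched-chain ketoacid breakdown (-2.92 ± 0.47), and VWF (-2.78 ± 0.57) fell as well. Most of the largest rises were in genes below background in the negative control, given here as lower bounds. TMEM151B was at least 11.2-fold higher, ZFYVE26 4.92-fold, the alpha-catenin CTNNA3 4.34-fold and CGA, the shared subunit of the pituitary glycoprotein hormones, 4-fold. The transcription factors FEZF2 and SOX2 were at least 3.49-fold and 3.44-fold higher, the calcium channel subunit CACNG7 2.79-fold and the contactin CNTN3 1.68-fold. NFATC1, a transcription factor of lymphocyte activation (3.07 ± 0.64), and MAOB, a monoamine oxidase (2.96 ± 0.46), rose too, each above background on 2 of the 3 negative control arrays. The adjusted p of these genes ran from 0.00318 to 0.045.

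Cell cycle genes stood higher with PHF (median 0.80, blocked 0.90, adjusted p = 2.33e-09, or 0.543 with an estimated correlation). Of 36 measured, 13 rose, 0 fell and 23 did not pass, and 26 rose adjusted over the list alone. Examples were RRM2, a subunit of ribonucleotide reductase (1.45 ± 0.34), GINS1 of the replication helicase (1.24 ± 0.24), BIRC5, an inhibitor of apoptosis at the spindle (1.1 ± 0.20), and TPX2, a spindle assembly factor (0.86 ± 0.20). The interferon response stood higher (median 0.67, blocked 0.38, adjusted p = 5.43e-07 or 0.543), 3 of 33 rising over all genes and 12 over the list alone, where 1 fell. Its risers were IRF1 (1.05 ± 0.26), LY6E (0.85 ± 0.17) and TAP2 (0.72 ± 0.16). Inflammatory cytokines and signalling genes stood higher (median 0.50, blocked 0.59, adjusted p = 2.47e-05 or 0.543), with 6 of 43 rising and 8 over the list alone. Among them were the chemokine CCL20 (1.15 ± 0.26), IL1B (0.75 ± 0.14) and IL22, 1.53-fold higher by the rule for bounds and above background on 2 of 3 PHF arrays. Macrophage, Kupffer cell and heterophil genes followed (median 0.32, blocked 0.30, adjusted p = 0.000537 or 0.543). Of 27, 2 rose, among them the goose-type lysozyme LYG2 (2.33 ± 0.48), and 9 rose over the list alone.

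Plasma proteins (median 0.32, blocked 0.36, adjusted p = 5.46e-05, or 0.543 with an estimated correlation, 3 of 36 rose) and hepatocyte genes (median 0.31, blocked 0.39, adjusted p = 0.00122 or 0.721, 3 of 29 rose) stood higher, among them ITIH2 (0.76 ± 0.14) and AMBP, a precursor of plasma glycoproteins (0.62 ± 0.12). The proteasome list stood higher (median 0.13, blocked 0.21, adjusted p = 0.0259 or 0.543, 4 of 36 rose), with PSMD1 (0.88 ± 0.16) and PSMA5 (0.67 ± 0.11). Lipoprotein and lipid transport genes stood higher as well (median 0.30, blocked 0.33, adjusted p = 0.0417 or 0.543). There PLIN3, a lipid droplet protein, was at least 2.52-fold higher and hepatic lipase LIPC fell (-1.57 ± 0.31). In this comparison 8 of 8 calls held with slide as a block. In lists without a call of their own, the mitochondrial chaperones HSPA9 (-1.08 ± 0.13) and HSPD1 (-1.04 ± 0.13) and the endoplasmic reticulum chaperone HSPA5 (-0.69 ± 0.13) fell. Of 41 genes of amino acid catabolism 5 fell and 2 rose (median -0.10, blocked -0.41, adjusted p = 0.559 or 0.967), the falls including the alanine aminotransferase GPT2 (-1.0 ± 0.14) and the ornithine aminotransferase OAT (-0.97 ± 0.18). PTDSS1, a phosphatidylserine synthase (-1.0 ± 0.21), ETNK2, an ethanolamine kinase (-0.52 ± 0.13), MVD of the mevalonate pathway (-0.93 ± 0.18), ACADL, an acyl-CoA dehydrogenase (-0.62 ± 0.14), and HEMGN (-1.46 ± 0.27) fell.

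The liver glycogen synthase GYS2 (1.04 ± 0.26), the plasma glutathione peroxidase GPX3 (0.98 ± 0.25) and thymidylate synthase TYMS (0.91 ± 0.19) rose with PHF. The lymphocyte receptors IL7R (1.01 ± 0.23) and CD40 (0.84 ± 0.13) rose too. The choline genes CHDH (-0.22 ± 0.12), BHMT (-0.28 ± 0.31), PEMT (0.26 ± 0.14), PCYT1A (-0.42 ± 0.12) and MAT1A (-0.034 ± 0.15) did not pass (adjusted p 0.0647 to 0.904). No gene passed by limma when slide was a fixed block (1817 at an unadjusted p under 0.05), where the error grew, and 941 did when it was a random block. ASNS went from -3.54 ± 0.40 to -4.11 ± 0.82, SLC6A9 to -4.45 ± 1.04, ALDH1L2 to -4.04 ± 0.85 and RRM2 to 1.90 ± 0.45. VWF (-0.34 ± 0.29) and NFATC1 (0.47 ± 0.96) lay closer to 0 in the fixed block. So did, as fitted values, CGA (0.53), CNTN3 (0.19), TMEM151B (0.66 ± 1.08), ZFYVE26 (0.46 ± 0.60), CACNG7 (-0.043 ± 1.0) and TUBAL3 (-0.28 ± 0.55). SOX2 (1.62 ± 0.61), CTNNA3 (3.64 ± 0.88) and FEZF2 (3.55 ± 1.07) moved less. Between the CCL arrays of the same slides, 1369 of the 2002 genes (68.4%) had the same sign. IL22, PLIN3 and CD40 reversed with normexp correction but stayed above the median gene. A further probe of TUBAL3 rose past the threshold, and 369 to 1564 genes passed with 1 array left out.

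**Figure D2:**
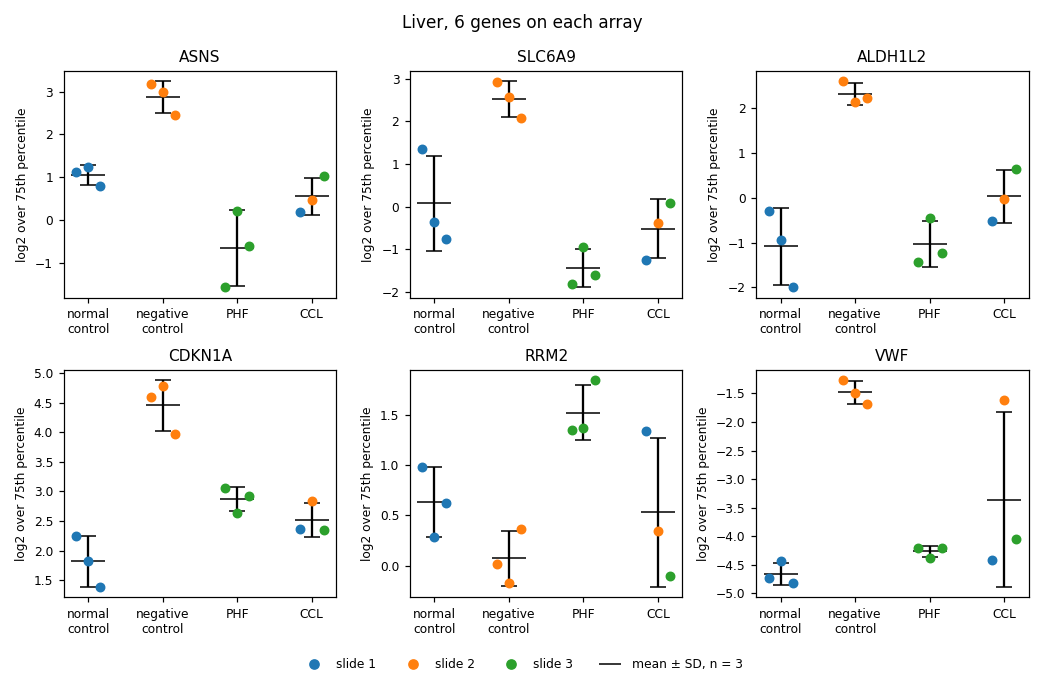
Log2 level (over each array's 75th percentile) of ASNS, SLC6A9, ALDH1L2, CDKN1A, RRM2 and VWF on each of the 12 liver arrays, with points for arrays, coloured by slide, and bars for the group mean ± SD (n = 3). ASNS, SLC6A9, ALDH1L2 and VWF were higher in the negative control than with PHF, RRM2 was lower, and VWF was also high on the CCL array that shared the slide of the negative control.

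CCL was set against the negative control likewise. Several genes that were low with PHF fell with CCL too, namely SLC6A9 (-3.04 ± 0.53), ASNS (-2.32 ± 0.40), HEMGN (-2.16 ± 0.27), PTDSS1 (-1.36 ± 0.21), GPT2 (-0.99 ± 0.14) and HSPA9 (-0.81 ± 0.13). CDKN1A (-1.93 ± 0.26) and BHLHA15, a transcription factor of secretory cells (-2.73 ± 0.41), fell as well. IL22, a cytokine that acts on epithelia, was at least 1.51-fold higher with CCL. AZIN2, an antizyme inhibitor of polyamine synthesis (1.07 ± 0.16), rose. The adjusted p of these 10 genes ran from 0.0309 to 0.0487.

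The interferon response stood higher with CCL (median 0.57, blocked 0.52, adjusted p = 8.93e-09, or 0.707 with an estimated correlation), 0 of 33 passing over all genes and 3 rising over the list alone, with LY6E at 0.78 ± 0.17 and IRF7 at 0.70 ± 0.19. Plasma proteins stood higher (median 0.28, blocked 0.34, adjusted p = 4.26e-08 or 0.707, 0 of 36 over all genes and 8 over the list alone), with the haem carrier HPX at 0.61 ± 0.17. Inflammation genes stood higher (median 0.39, blocked 0.51, adjusted p = 5.82e-06 or 0.707, 1 of 43 and 3 alone), IL22 being the member that passed and CCL20 lying at 1.44 ± 0.26. Hepatocyte genes (median 0.28, blocked 0.31, adjusted p = 2.51e-05 or 0.807) and macrophage, Kupffer cell and heterophil genes (median 0.31, blocked 0.23, adjusted p = 0.000489 or 0.707) followed, with 0 members past the threshold by limma and LYG2 at 1.96 ± 0.48. Within the shared slide 5 of the 5 calls held. The choline genes CHDH (-0.33 ± 0.12), BHMT (-0.14 ± 0.31), PEMT (-0.14 ± 0.14), PCYT1A (-0.029 ± 0.12) and MAT1A (-0.10 ± 0.15) did not pass. In all, 86 passed, 25 higher and 61 lower with CCL. Within the slide that both groups shared none passed by limma (2119 at an unadjusted p under 0.05, and 41 genes with a random block), with SLC6A9 at -2.91 ± 0.73, ASNS at -2.42 ± 0.58 and CDKN1A at -1.61 ± 0.38. With normexp correction IL22 lay at -0.01, still above the median gene. SLC6A9 reversed to 0.78 in the deposited table, and leaving out 1 array gave 0 to 255 genes.

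PHF was set against CCL to compare these groups with each other. CTNNA3 and FEZF2 were at least 3.96-fold and 3.18-fold higher with PHF, and the orphan receptor GPR52 at least 1.26-fold. ANXA6, a membrane-binding annexin (-1.66 ± 0.25), the Rab regulator TBC1D13 (-1.49 ± 0.15) and the tropomyosin TPM3 (-0.94 ± 0.14) were lower. Over these 6 genes the adjusted p ran from 0.00403 to 0.0339. Cell cycle genes stood higher as a list (median 0.59, blocked 0.75, adjusted p = 1.12e-10, or 0.971 with an estimated correlation) although 0 of 36 passed by limma, GINS1 lying at 0.90 ± 0.24 and the replication licensing gene MCM2 at 0.79 ± 0.25. The proteasome (median 0.17, blocked 0.19, adjusted p = 0.000316 or 0.861) and oxidative phosphorylation (median 0.11, blocked 0.088, adjusted p = 0.0135 or 0.971) lists stood higher, with PSMC3 at 0.35 ± 0.12 and UQCRB at 0.34 ± 0.16. The unfolded protein and stress list stood lower (median -0.14, blocked -0.13, adjusted p = 0.0271 or 0.861), with HSPA5 at -0.65 ± 0.13. Of these 4 calls 2 held within the shared slide. A total of 60 passed, 10 higher and 50 lower with PHF, against 6 within their shared slide and 47 with a random block, where TBC1D13 lay at -1.74 ± 0.18, CTNNA3 at 3.84 ± 0.62 and ANXA6 at -1.81 ± 0.38. With 1 array left out 16 to 132 passed.

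PHF was also set against the normal control. CTNNA3, FEZF2 and UNC80, a part of the sodium leak channel complex, were at least 3.96-fold, 3.18-fold and 1.4-fold higher with PHF. ALAS1, the first enzyme of haem synthesis (2.18 ± 0.33), rose. The calcium pump ATP2B2 (-3.05 ± 0.47) and ANXA6 (-1.94 ± 0.25) fell, and SLC1A6 was at least 2.09-fold lower. GLDC, the glycine decarboxylase (-1.04 ± 0.20), SHMT1, a serine hydroxymethyltransferase (-0.77 ± 0.14), GPT2 (-0.86 ± 0.14), ETNK2 (-0.82 ± 0.13), MVD (-0.95 ± 0.18), THRB (-0.98 ± 0.15) and HSPD1 (-0.65 ± 0.13) fell as well. In all, 584 passed, 356 higher and 228 lower with PHF, but 231 and 256 with quantile normalization. With slide as a random block 154 passed, and as a fixed block none did by limma (1513 at an unadjusted p under 0.05), where CTNNA3 lay at 3.86 ± 0.88, ALAS1 at 3.21 ± 0.53, GLDC at -1.02 ± 0.44 and UNC80, as a fitted value, at 0.39 ± 0.36 from 2.73 ± 0.51. From 33 to 337 passed when 1 array was left out.

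Cell cycle genes stood higher than in the normal control (median 0.68, blocked 1.31, adjusted p = 1.38e-06, or 0.76 with an estimated correlation). Of 36, 4 rose over all genes, with 19 rising and 1 falling over the list alone, and the mitotic kinesin KIF20A (1.22 ± 0.24) and the kinase AURKA (1.18 ± 0.25) among them. Ribosomal proteins (median 0.21, blocked 0.18, adjusted p = 1.38e-06 or 0.789), inflammation (median 0.37, blocked 0.18, adjusted p = 0.00137 or 0.723) and macrophage genes (median 0.40, blocked 0.47, adjusted p = 0.00137 or 0.723) stood higher, with RPL3L (1.03 ± 0.20) and the prostaglandin synthase PTGS2 (0.84 ± 0.19) among the members that rose. The interferon response (median 0.40, blocked 0.068, adjusted p = 0.00551 or 0.789), erythroid genes (median 0.92, blocked 1.52, adjusted p = 0.0174 or 0.789) and lymphocyte genes (median 0.40, blocked 0.52, adjusted p = 0.0198 or 0.789) stood higher too, and CD40 rose (0.64 ± 0.13). Heat shock proteins (median -0.17, blocked -0.065, adjusted p = 0.00191 or 0.723) and gluconeogenesis and glycogen genes (median -0.24, blocked -0.14, adjusted p = 0.00219 or 0.35) stood lower. The unfolded protein and stress list (median -0.14, blocked 0.051, adjusted p = 0.00219 or 0.437) and cholesterol synthesis (median -0.36, blocked -0.25, adjusted p = 0.0232 or 0.789) stood lower as well. Of the 11 calls 5 held with slide as a block.

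Between CCL and the normal control 0 genes passed by limma, with 2640 at an unadjusted p under 0.05. ATP2B4, a calcium pump (1.08 ± 0.17), the platelet glycoprotein GP1BB (0.96 ± 0.15, above background on 1 of 3 normal control arrays) and IFT80 of the cilium (-1.05 ± 0.16) were among the smallest p values. GPT2 (-0.85 ± 0.14) was too, and the adjusted p of the 4 ran from 0.122 to 0.124. Ribosomal proteins (median 0.19, blocked 0.22, adjusted p = 5.62e-07, or 0.767 with an estimated correlation), inflammation (median 0.34, blocked 0.22, adjusted p = 0.00441 or 0.725) and macrophage genes (median 0.28, blocked 0.33, adjusted p = 0.00462 or 0.725) stood higher with CCL as lists, with ACOD1, the itaconate-forming enzyme of macrophages, at 2.00 ± 0.34. Erythroid genes (median 0.50, blocked 0.68, adjusted p = 0.00613 or 0.767) and the interferon response (median 0.28, blocked 0.17, adjusted p = 0.0133 or 0.767) stood higher too, with the alpha-globin HBAD at 1.15 ± 0.29. Heat shock proteins stood lower (median -0.20, blocked -0.16, adjusted p = 4.5e-06 or 0.339), with HSP90AA1 at -0.65 ± 0.18. The list of choline and phospholipid genes had a call as well (median 0.016, blocked -0.017, adjusted p = 0.0486 or 0.339). CHDH lay at -0.59 ± 0.12 and PEMT at -0.62 ± 0.14, past the threshold over their list alone and not over all genes (adjusted p = 0.186 and 0.197). Plasma proteins (median 0.15, blocked 0.16, adjusted p = 0.0186 or 0.767), hepatocyte (median 0.13, blocked 0.15, adjusted p = 0.0493 or 0.77) and endothelial genes (median 0.25, blocked 0.024, adjusted p = 0.0454 or 0.725) stood higher. Methionine and one-carbon metabolism (median -0.091, blocked -0.099, adjusted p = 0.0493 or 0.767), fatty acid synthesis (median -0.071, blocked -0.025, adjusted p = 0.0493 or 0.767), gluconeogenesis and glycogen (median -0.10, blocked -0.12, adjusted p = 0.00613 or 0.339), oxidative phosphorylation (median -0.059, blocked 0.019, adjusted p = 0.0114 or 0.78) and the proteasome (median -0.066, blocked -0.037, adjusted p = 0.0181 or 0.725) stood lower. Of the 15 calls 7 held within the shared slide. Within the shared slide 6 genes passed, against 0 without the block. Leaving out 1 array raised that count to at most 22, without CCL 1.

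In breast muscle the control groups differed in 4 of 20836 genes and probes. WT1, a transcription factor of kidney, gonad and mesothelium, was at least 2.72-fold higher in the negative control (adjusted p = 0.029) and CXCR1, a chemokine receptor of heterophils, at least 2.09-fold (0.0134). BPIFB3, above background on 1 of 3 negative control arrays, was 1.27-fold higher by the rule for bounds (0.00422). The remaining feature, a probe without a gene name that the array design calls GT_EA746_A_87_P014133, fell by 2.25 on the log2 scale. Genes of slow and cardiac muscle stood lower in the negative control (median -0.68, blocked -0.98, adjusted p = 0.000769, or 0.987 with an estimated correlation), 0 of 20 passing over all genes and 3 falling over the list alone. The muscle LIM protein CSRP3 lay at -5.09 ± 0.85 (above background on 1 of 3 negative control arrays), phospholamban PLN at -2.89 ± 0.46 and ANKRD2 at -2.04 ± 0.62. Ribosomal proteins stood lower (median -0.085, blocked 0.0092, adjusted p = 0.0138 or 0.987), RPS3 lying at -0.37 ± 0.13. Of both calls 1 held with slide as a block. With slide as a block no gene passed by limma (872 at an unadjusted p under 0.05), the fitted values of WT1 and CXCR1 being 3.94 ± 0.93 and 1.46 ± 0.31. Normexp correction reversed CXCR1 and BPIFB3, and 0 to 22 genes passed with 1 array left out.

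With PHF against the negative control 3 of 20835 passed in muscle. WT1 was at least 3.07-fold lower (adjusted p = 0.0176), and 2 unnamed probes, GT_EA746_A_87_P022163 and GT_EA746_A_87_P064621, rose by 3.93 and 1.57. The interferon response list stood higher (median 1.24, blocked 0.77, adjusted p = 1.56e-17, or 0.638 with an estimated correlation), with 0 of 33 past the threshold over all genes and 20 rising over the list alone. Its members with the smallest p were the antiviral GTPase MX1 (2.39 ± 0.51), the peptide transporter TAP1 (1.89 ± 0.46) and the ADP-ribosyltransferases PARP14 (1.49 ± 0.34) and PARP12 (1.29 ± 0.31). Macrophage genes (median 0.90, blocked 0.98, adjusted p = 6.79e-07 or 0.787) and inflammation (median 0.41, blocked 0.14, adjusted p = 6.22e-05 or 0.787) stood higher, with the oxidase subunit CYBB at 1.78 ± 0.57 and the receptor TLR7 at 1.43 ± 0.60. Lymphocyte genes stood higher (median 0.50, blocked 0.064, adjusted p = 0.000192 or 0.787), with the chemokine receptor CXCR4 at 1.25 ± 0.31 (above background on 1 of 3 negative control arrays). Plasma proteins (median 0.69, blocked 0.53, adjusted p = 9.7e-07 or 0.638) and hepatocyte genes (median 0.55, blocked 0.24, adjusted p = 0.00801 or 0.787) stood higher, with ORM1 at 0.67 ± 0.17 and complement C3 at 1.70 ± 0.71. So did slow muscle genes (median 0.74, blocked 0.56, adjusted p = 0.000896 or 0.787) and the cell cycle (median 0.25, blocked 0.058, adjusted p = 0.000689 or 0.787), with CSRP3 at 2.36 ± 0.85 (above background on 1 of 3 negative control arrays) and BIRC5 at 0.62 ± 0.22. The medians of the interferon, macrophage and lymphocyte lists were highest on array PHF 2, the array least like its own group. Relative to the negative control mean, the interferon median was 1.75 on PHF 2, 0.82 on PHF 1 and 0.63 on PHF 3, with 0.66 on the CCL array of their slide. Without PHF 2 the median was 0.0826 for hepatocyte genes and 0.33 for plasma proteins, and on PHF 3 both lay below the negative control mean.

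Oxidative phosphorylation genes stood lower in muscle with PHF (median -0.30, blocked -0.23, adjusted p = 5.47e-12, or 0.787 with an estimated correlation), with 0 of 65 past the threshold over all genes and 10 falling over the list alone. ATP5I of the ATP synthase lay at -0.53 ± 0.13, cytochrome c (CYCS) at -0.51 ± 0.14 and SDHB of succinate dehydrogenase at -0.42 ± 0.12. The proteasome stood lower as well (median -0.20, blocked -0.13, adjusted p = 0.000896 or 0.794). Fast muscle contraction (median -0.20, blocked -0.16, adjusted p = 0.0306 or 0.794) and ribosomal proteins (median -0.093, blocked -0.06, adjusted p = 0.0435 or 0.914) stood lower, with list means that turned positive under quantile normalization (0.045 and 0.031). Of the 12 calls 1 held with slide as a block, oxidative phosphorylation (adjusted p = 0.00259), with the interferon response at 0.186. The choline genes BHMT (0.029 ± 0.14), PEMT (-0.24 ± 0.16), PCYT1A (-0.34 ± 0.19) and MAT1A (0.18 ± 0.26) did not pass. Under the slide block, which rests on CCL 3, scanned on another day, WT1 lay at a fitted -4.43 ± 0.93, MX1 at 1.99 ± 1.1 and ATP5I at -0.51 ± 0.26. With a random block 1 passed. CXCR4 reversed with normexp correction, and 1 to 16 genes passed with 1 array left out.

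**Figure D3:**
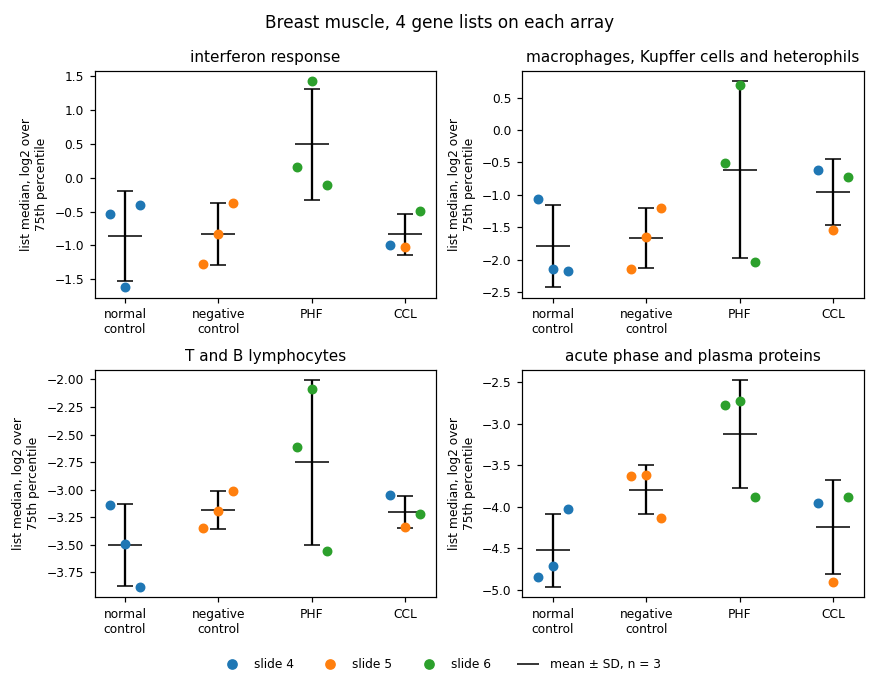
Median log2 level of the interferon response, macrophage, lymphocyte and plasma protein lists on each of the 12 breast muscle arrays, with points for arrays, coloured by slide, and bars for the group mean ± SD (n = 3).

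CCL against the negative control passed 3 in muscle. WT1 was at least 3.2-fold lower (adjusted p = 0.0423), and the unnamed probes GT_EA746_A_87_P022163 and GT_EA746_A_87_P014133 rose by 3.91 and 2.23. Slow and cardiac muscle genes stood higher with CCL (median 0.85, blocked 0.88, adjusted p = 3.23e-05, or 0.788 with an estimated correlation), CSRP3 lying at 3.28 ± 0.85 and the myosin MYH7B at 2.36 ± 0.69 (each above background on 1 of 3 negative control arrays). Oxidative phosphorylation stood lower (median -0.23, blocked -0.21, adjusted p = 0.000152 or 0.788), with ATP5C1 at -0.38 ± 0.13. The interferon response (median 0.40, blocked 0.26, adjusted p = 0.00313 or 0.788), macrophage (median 0.41, blocked 0.31, adjusted p = 0.0128 or 0.788), extracellular matrix (median 0.14, blocked 0.18, adjusted p = 0.0362 or 0.788) and inflammation (median 0.21, blocked 0.082, adjusted p = 0.0467 or 0.788) lists stood higher, with the macrophage receptor TIMD4 at 1.28 ± 0.34 and the matrix protein TNC at 0.72 ± 0.30. No member of these lists passed by limma over all genes or over the list alone, and 3 of the 6 calls held within the shared slide. Within the shared slide WT1 lay at a fitted -3.79 ± 0.66, and no gene passed by limma (913 at an unadjusted p under 0.05). In the deposited table ATP5C1 lay at 0.47, with its sign reversed, and 920 genes passed without CCL 2, against 1 to 19 without any other array.

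PHF against CCL passed 8 in muscle, all higher with PHF and 6 of them unnamed. The synaptotagmin SYT16 was at least 2.12-fold higher (adjusted p = 0.0495) and SLCO1B1, an organic anion transporter of liver, rose (1.55 ± 0.20, 0.0495). The interferon response list stood higher (median 0.81, blocked 0.57, adjusted p = 1.89e-07, or 0.793 with an estimated correlation, 3 of 33 rose over the list alone), with MX1 at 2.06 ± 0.51 and SAMD9L at 2.29 ± 0.68. Hepatocyte genes (median 1.14, blocked 0.81, adjusted p = 0.00281 or 0.793, 2 alone) and plasma proteins (median 0.85, blocked 0.71, adjusted p = 0.00472 or 0.793, 3 alone) stood higher as well, with fibrinogen FGB at 1.26 ± 0.40 and ORM1 at 0.98 ± 0.17. The lymphocyte (median 0.43, blocked 0.50, adjusted p = 0.00598 or 0.793) and cell cycle (median 0.21, blocked 0.16, adjusted p = 0.00281 or 0.793) lists did too, with CXCR5 at 1.28 ± 0.33 and AURKA at 0.90 ± 0.24. The lymphocyte, hepatocyte and plasma protein medians were highest on PHF 2, which stood apart (levels -2.09, -2.84 and -2.73), and on PHF 3 they were -3.56, -4.73 and -3.88, at or below the highest CCL array, while 1 gene passed without PHF 2. Extracellular matrix (median -0.19, blocked -0.28, adjusted p = 0.00598 or 0.793) and oxidative phosphorylation (median -0.09, blocked -0.055, adjusted p = 0.011 or 0.793) stood lower, with SPARC at -0.40 ± 0.15 and NDUFB2 at -0.33 ± 0.13. By camera 0 of the 7 calls held within the shared slide. Within the shared slide, where the 3 PHF arrays met CCL 3 alone, SYT16 lay at 1.72 and SLCO1B1 at 1.71. With a random block 2 passed. CCL 3 was scanned on another day than the rest, so the blocked values cannot separate slide from scan day. SYT16 reversed with normexp correction and SLCO1B1 in the deposited table, and 1139 genes passed without CCL 2, against 1 to 20 without any other array.

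The most genes in muscle passed between PHF and the normal control (374 of 20835, 332 higher and 42 lower). POMP, a proteasome assembly factor, STEAP4, a metalloreductase, CXCR1 and the testis kinase TSSK6 were at least 4.54-fold, 2.96-fold, 2.89-fold and 1.73-fold higher. Genes of macrophages and heterophils stood higher as a list (median 1.26, blocked 1.84, adjusted p = 8.78e-08, or 0.663 with an estimated correlation), 3 of 25 rising over all genes and 5 over the list alone. The risers were CXCR1, CYBB of the phagocyte oxidase (2.72 ± 0.57, above background on 2 of 3 normal control arrays) and the transcription factor IRF8 (1.23 ± 0.22). The macrophage median was 0.70 on PHF 2, which stood apart, and -2.03 on PHF 3, within the normal control range (-2.18 to -1.06), and 4 of the 374 genes passed without PHF 2. The interferon response stood higher (median 1.22, blocked 0.93, adjusted p = 1.06e-12 or 0.663), 2 of 33 rising over all genes, IRF8 and HELZ2 (1.19 ± 0.20), and 23 over the list alone. Plasma proteins stood higher (median 1.24, blocked 1.15, adjusted p = 8.78e-08 or 0.663), 2 of 26 rising over all genes, ORM1 (1.11 ± 0.17) and kininogen KNG1 (1.09 ± 0.20), and 11 over the list alone. TLR5, the flagellin receptor, was at least 1.33-fold higher on the 2 of 3 PHF arrays above background. PLN (-2.21 ± 0.46) fell, and ABCC2, an export pump for conjugates, was at least 1.72-fold lower. The adjusted p of these 12 genes ran from 0.0015 to 0.043.

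Lymphocyte (median 0.95, blocked 1.26, adjusted p = 1.5e-06, or 0.663 with an estimated correlation), inflammation (median 0.46, blocked 0.78, adjusted p = 8.86e-05 or 0.663) and cell cycle (median 0.30, blocked 0.22, adjusted p = 0.00305 or 0.663) genes stood higher in muscle with PHF than in the normal control. Hepatocyte genes did too (median 1.34, blocked 1.1, adjusted p = 3.78e-05 or 0.663), from low normal control levels (-5.57 to -4.87, 29 genes). Of 20, 0 passed, and 11 rose over the list alone, with APOH at 1.83 ± 0.42. The lymphocyte median was -2.09 on PHF 2 and -3.56 on PHF 3, within the normal control range (-3.88 to -3.14). Oxidative phosphorylation (median -0.21, blocked -0.077, adjusted p = 3.85e-06 or 0.663), ribosomal proteins (median -0.19, blocked -0.032, adjusted p = 3.88e-06 or 0.805) and heat shock proteins (median -0.25, blocked -0.31, adjusted p = 0.00056 or 0.663) stood lower, with NDUFC2 at -0.45 ± 0.13 and the heat shock factor HSF2 at -0.57 ± 0.14. The proteasome (median -0.16, blocked -0.18, adjusted p = 0.0098 or 0.805) and fast muscle contraction (median -0.17, blocked 0.12, adjusted p = 0.0174 or 0.805) stood lower as well. With the slide block 6 of the 12 calls held. Under the slide block, which rests on CCL 3 here too, CXCR1 lay at 2.91 ± 0.31, TSSK6 at 2.88 ± 0.26 and STEAP4 at 2.32 ± 1.32. With a random block 3 passed. After normexp correction 0 passed by limma (1440 at an unadjusted p under 0.05). With it STEAP4, CXCR1, TSSK6, TLR5, POMP (near the median gene) and APOH (above it) reversed, and lists were not rerun. IRF8 reversed in the deposited table, and leaving out 1 array gave 3 to 73 genes, or 366 without PHF 3.

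Between CCL and the normal control 1 unnamed probe, GT_EA746_A_87_P022163, passed in muscle, higher with CCL by a log2 change of 4.09. LRRC73 (0.99 ± 0.15, adjusted p = 0.16) and CXCR1, at least 1.24-fold higher on the 2 of 3 CCL arrays above background (0.16), did not pass. Macrophage genes stood higher as a list (median 0.94, blocked 1.21, adjusted p = 8.88e-08, or 0.692 with an estimated correlation), 0 of 25 passing over all genes and 3 rising over the list alone, with TIMD4 at 1.20 ± 0.34 and IRF8 at 1.16 ± 0.22. The interferon response (median 0.44, blocked 0.24, adjusted p = 0.000557 or 0.722), plasma proteins (median 0.47, blocked 0.58, adjusted p = 0.000654 or 0.692) and inflammation (median 0.29, blocked 0.41, adjusted p = 0.00377 or 0.722) stood higher. Lymphocyte (median 0.36, blocked 0.62, adjusted p = 0.00518 or 0.722) and bile duct and stellate cell (median 0.23, blocked 0.24, adjusted p = 0.0426 or 0.692) genes did too. Ribosomal proteins (median -0.14, blocked -0.082, adjusted p = 1e-05 or 0.722), oxidative phosphorylation (median -0.098, blocked -0.06, adjusted p = 0.00518 or 0.722) and the proteasome (median -0.12, blocked -0.12, adjusted p = 0.0488 or 0.723) stood lower. Of the 9 calls 5 held within the shared slide. CXCR1 reversed with normexp correction, as LRRC73 and TIMD4 did in the deposited table.

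Whether the PHF change differed between the tissues was tested as the liver change minus the muscle change, each against the negative control, over all 24 arrays. The change in liver lay below that in muscle for SLC6A9 (-4.42 ± 0.77), ASNS (-3.80 ± 0.82), ALDH1L2 (-3.27 ± 0.52), MPP2 (-3.11 ± 0.60), the histidine-degrading enzyme UROC1 (-2.01 ± 0.42) and OAT (-0.99 ± 0.23). It lay above that in muscle for TMEM151B (5.60 ± 1.12), WT1 (3.91 ± 0.64), the urotensin receptor UTS2R (3.42 ± 0.78), HYALP1 (3.38 ± 0.65) and IL22 (3.03 ± 0.72). The same held for AMP deaminase AMPD1 (2.42 ± 0.55), the lipase PNPLA2 (2.15 ± 0.51), the proteasome genes PSMD1 (1.1 ± 0.23) and PSMA5 (1.02 ± 0.19) and SELENOI of phosphatidylethanolamine synthesis (1.05 ± 0.23). RRM1 (0.85 ± 0.20) and ATP5I (0.67 ± 0.16) were also above, and the adjusted p over these 18 genes ran from 0.0124 to 0.0499. TMEM151B and IL22 lay below background in the liver of the negative control and WT1 in the muscle of PHF birds, so their values are fitted ones and not folds. In all, 252 of 23332 passed, 149 with the liver change above the muscle change and 103 below it, a balance that was 107 to 164 with the percentile over detected probes and 77 to 92 in the deposited table. With slide as a block, a fit chosen after seeing the data, 49 passed, only 7 of them among the 252, and 249 of the 252 had the same sign. ASNS, at -7.37 ± 1.22, was the only 1 of the 18 named genes to pass, SLC6A9 then lay at -5.92 ± 1.57, ALDH1L2 at -4.48 ± 1.01 and PSMA5 at 1.49 ± 0.32, and UTS2R (0.84 ± 1.16) and PSMD1 (0.49 ± 0.47) lay closer to 0. Leaving out 1 array gave 34 to 427 genes, and normexp correction gave 2.

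As lists, oxidative phosphorylation (median 0.35, adjusted p = 3.62e-08 or 0.951 with an estimated correlation), the proteasome (0.34, 2.9e-05 or 0.951) and the cell cycle (0.51, 0.000101 or 0.951) stood higher in the difference between tissues. Of their members, 1 of 65, 2 of 36 and 1 of 36 passed over all genes, and 7, 7 and 2 over the list alone. Ribosomal proteins stood higher by 75th percentile scaling (median 0.12, mean 0.14, adjusted p = 0.0494 or 0.951) and lower by quantile normalization (mean -0.13). The interferon response (-0.37, 0.0327 or 0.951) and lymphocyte genes (-0.36, 0.0433 or 0.951) stood lower. Of these 6 calls 1 held with slide as a block.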

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

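The tests of slide, shared arrays, the stress list, single arrays, liver RNA and other splits of the arrays in this part were chosen after seeing the result, while the difference between tissues and the slide check were planned. Groups of 3 arrays were not tested for outlying samples.

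The PHF change against the negative control differed between liver and breast muscle, tested as an interaction over 24 arrays, for 252 genes (34 to 427 with 1 array left out, the fewest without liver negative control 2, and 7 of the 252 with slide as a block). The named ones, as the liver change minus the muscle change in log2, were SLC6A9 (-4.42), ASNS (-3.80), ALDH1L2 (-3.27), MPP2 (-3.11), UROC1 (-2.01), OAT (-0.99), TMEM151B (5.60), WT1 (3.91), UTS2R (3.42), HYALP1 (3.38), IL22 (3.03), AMPD1 (2.42), PNPLA2 (2.15), PSMD1 (1.1), SELENOI (1.05), PSMA5 (1.02), RRM1 (0.855) and ATP5I (0.67). By camera on that contrast the medians of the cell cycle (0.51), oxidative phosphorylation (0.35), proteasome (0.34) and ribosomal protein (0.12, with a mean of -0.13 after quantile normalization) lists lay above 0 and those of the interferon response (-0.37) and lymphocyte (-0.36) lists below it, calls that were all lost at adjusted p = 0.951 with an estimated correlation and of which 1 of 6 held with slide as a block. Of 100 drawn splits, 6 gave as many genes, but splits could keep the real liver groups, so this cannot judge chance. The highest (1362) exchanged PHF and negative control in muscle alone, which tests the sum of both tissues' changes, not their difference.

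In liver, 2002 genes differed between PHF and the negative control, which lay on different slides (369 to 1564 with 1 array left out). Over these genes the CCL arrays of the same slides differed by a median of 0.22 of the group difference (other orders -0.219 to 0.219). Slide as the whole cause would give about 0.884, allowing only for the choice of large differences. For muscle PHF against the normal control the ratio was -0.0436 against 0.796 (other orders -0.474 to 0.474). It rests on CCL 3, scanned on another day. Over all liver genes the slide share of the variance beyond error was 0.721 (other orders -0.431 to 0.431), which leaves 1 possible. The slide block subtracts the CCL differences, so its median ratio of 0.779 and 1890 of 2002 kept signs (94.4%) restate the 0.22. With it 0 passed by limma (1817 at an unadjusted p under 0.05). Neither ratio excludes slide, since the fit that chose the genes takes CCL spread over slides as error, which favours low ratios. Slides may cause the larger part of the differences over all genes, and diet stays open as untested.

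In liver, 79 genes differed between the negative control and both the normal control and PHF, 67 of them higher and 12 lower in the negative control, among them ALDH1L2. Slide as the whole cause would set that slide's CCL array apart by about 0.883 of the negative control's distance. Its median ratio was 0.0782, beside -0.163 and -0.0212 for the other CCL arrays. The fit favours genes with small CCL spread, so this cannot exclude slide. Noise of the shared negative control would give a covariance of the changes from -0.0612 to -0.0483 over 50 simulations without change, and it was -0.157, but they held no slide shift, and slide, with a share of 0.898 and 0.721 over all genes, may have added to it. The 79 genes in common stood against 4.77 for independent lists and 61 for simulated lists of the same lengths (highest 74), and since 3 control arrays cannot be split, part of that excess may come from the shared arrays. The list of unfolded protein and stress genes had a camera adjusted p of 0.127, which cannot tell whether a stress response in the negative control was involved, and the diet of that group stays open as untested.

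In breast muscle the interferon response, macrophage and lymphocyte lists stood higher with PHF than in the negative control (medians 1.24, 0.91 and 0.51, for the last 2 lists over 26 and 28 members, 1 more in each than camera tested), calls that were lost at adjusted p = 0.638, 0.787 and 0.787 with an estimated correlation and at 0.186, 0.092 and 0.467 with slide as a block, and array PHF 2 had the highest level of each. Without PHF 2 the medians were 0.799, 0.376 and 0.121. For the interferon response the other PHF arrays (0.818 and 0.632) lay above the highest negative control array (0.369), so PHF 2 was not the whole cause, while for macrophages and lymphocytes PHF 3 (-0.142 and -0.0109) lay within the control range and that array may account for the rise. Liver RNA in the samples would have to make up 21.5% of the liver level for the interferon list and 29.9% for the macrophage list, while hepatocyte genes rose by 0.0174% of theirs, which argues against liver RNA as the source. More immune cells in that sample and diet stay open as untested, and so does slide for the interferon response, since CCL 3 on the PHF slide stood at 0.655, above PHF 3, and CCL 1 and CCL 2 at 0.241 and 0.261.

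For comparisons of 3 arrays with 3, the 10 splits of the 6 arrays are too few for a share under 0.05. In liver, 1 of the 10 splits, the real one, gave as many genes for the negative control against the normal control (109, highest other 2), PHF against the negative control (2002, 0), CCL against the negative control (86, 7) and PHF against the normal control (584, 1). For PHF against CCL 2 of the 10 did, with 60 genes against 482 in a split that set PHF 2, PHF 3 and CCL 3 against PHF 1, CCL 1 and CCL 2. The first 3 and PHF 1 shared a slide and CCL 1 and CCL 2 lay on others, so slide was not excluded as a part of that structure, and within the shared slide 6 genes passed. For CCL against the normal control 10 of the 10 did, since 0 passed by limma (2640 at an unadjusted p under 0.05, highest other 5). In muscle, 1 of the 10 did so for the negative control against the normal control (4, highest other 0), CCL against the negative control (3, 2), PHF against CCL (8, 2), PHF against the normal control (374, 0) and CCL against the normal control (1, 0). For muscle PHF against the negative control 2 of the 10 did (3, highest other 3).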

How the results depend on the processing

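Alternatives were run 1 at a time, and 4 of the tests were chosen after seeing the result: slide as a block for the difference between tissues, muscle CCL 3 left out, slide as a block without muscle CCL 3, and muscle PHF 2 left out. Counts of changed genes are listed for each tissue in the order negative control against normal control, PHF against negative control, CCL against negative control, PHF against CCL, PHF against normal control and CCL against normal control. As reported they were 109, 2002, 86, 60, 584 and 0 in liver, 4, 3, 3, 8, 374 and 1 in muscle and 252 for the difference between tissues. The 53 counts of 0 below come from limma fits with 373 to 3751 features at an unadjusted p under 0.05. Some splits into higher and lower that moved by over 10 points, with at least 5 genes in both settings, are given. Unless a reason is given, the cause was not tested.

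Normexp background correction with an offset of 50 gave 269, 841, 40, 8, 19 and 0 in liver, 0, 0, 0, 0, 0 and 0 in muscle and 2 for the difference between tissues. It moved the median log2 change of all genes to 0.19, -0.11, -0.086, -0.024, 0.10 and 0.12 in liver, -0.10, -0.19, -0.037, -0.15, -0.23 and -0.13 in muscle and 0.12 for the difference between tissues, and single values below include that shift. The split moved for liver PHF against negative control (340 higher and 501 lower, from 1054 and 948), liver CCL against negative control (4 higher and 36 lower, from 25 and 61), liver PHF against CCL (0 higher and 8 lower, from 10 and 50) and liver PHF against normal control (3 higher and 16 lower, from 356 and 228). Quantile normalization gave 116, 2071, 107, 72, 487 and 0 in liver, 12, 3, 4, 1, 156 and 1 in muscle and 284 for the difference between tissues. The split moved for liver negative control against normal control (80 higher and 36 lower, from 88 and 21) and liver PHF against normal control (231 higher and 256 lower, from 356 and 228). Scaling by the 75th percentile of probes well above background gave 118, 1930, 84, 74, 573 and 0 in liver, 5, 9, 3, 19, 621 and 1 in muscle and 271 for the difference between tissues. The split moved for the difference between tissues (107 and 164, from 149 and 103). Starting from the deposited table of log2 values gave 88, 1618, 41, 53, 524 and 3 in liver, 4, 3, 2, 22, 244 and 1 in muscle and 169 for the difference between tissues. The split moved for the difference between tissues (77 and 92, from 149 and 103).

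No filter on dim probes, which tests more features, gave 12, 1388, 13, 54, 323 and 0 in liver, 7, 4, 1, 3, 93 and 1 in muscle and 162 for the difference between tissues. Testing only features above background on every array gave 203, 1858, 169, 51, 440 and 0 in liver, 0, 0, 0, 0, 264 and 0 in muscle and 356 for the difference between tissues. Testing every probe on its own, which counts a gene several times, gave 240, 3585, 208, 184, 1205 and 0 in liver, 4, 3, 1, 2, 367 and 1 in muscle and 427 for the difference between tissues. The mean of a gene's probes gave 105, 2037, 89, 70, 664 and 0 in liver, 4, 3, 3, 2, 415 and 1 in muscle and 219 for the difference between tissues. Keeping outlier spots gave 103, 1992, 86, 59, 584 and 0 in liver, 4, 3, 3, 2, 370 and 1 in muscle and 252 for the difference between tissues. A further threshold of 2-fold, which can lower counts and not raise them, gave 60, 783, 39, 46, 313 and 0 in liver, 4, 3, 3, 8, 302 and 1 in muscle and 184 for the difference between tissues.

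A trended and robust prior gave 370, 2346, 202, 56, 645 and 0 in liver, 0, 1, 1, 0, 389 and 1 in muscle and 395 for the difference between tissues. Array weights gave 1531, 2545, 173, 20, 808 and 0 in liver, 1290, 4, 2015, 1050, 1064 and 116 in muscle and 632 for the difference between tissues. Fits of the 6 arrays compared, which leave fewer degrees of freedom, gave 1022, 1436, 0, 5, 427 and 0 in liver and 670, 0, 0, 0, 822 and 2 in muscle. A fit of all 24 arrays gave 277, 1680, 150, 12, 559 and 15 in liver and 180, 89, 35, 241, 1088 and 21 in muscle. Without muscle CCL 3 the 6 muscle counts were 183, 9, 1, 1, 931 and 2, and without muscle PHF 2 they were 2, 1, 1, 1, 4 and 1.

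Slide as a fixed block gave 0, 0, 0, 6, 0 and 6 in liver and 0, 295, 0, 1510, 354 and 1 in muscle. Slide as a random block gave 0, 941, 41, 47, 154 and 0 in liver and 1, 1, 1, 2, 3 and 1 in muscle. For the difference between tissues the fixed block gave 49. Without muscle CCL 3 the fixed block gave 0 for muscle negative control against normal control, 0 for muscle CCL against negative control and 1 for muscle CCL against normal control. In liver PHF against the negative control the fixed block raised the median standard error from 0.193 to 0.367. The check of liver slides stood at a mean r of 0.399, and at 0.3 over features above background on every array and 0.384 after quantile normalization. The muscle values were 0.0592, 0.0547 and 0.0557, and for the muscle pair without CCL 3 r was 0.302, 0.28 and 0.275.

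The labels share only a number between arrays, and the check did not pair them by the rule that every pair lie over 0.1: 5 liver and 4 muscle arrays of 12 correlated best with an array of their own number. Within a tissue the residuals of arrays with the same number had a median r of 0.0229 in liver and 0.011 in muscle, against -0.0219 and 0.00245 for other numbers. Between tissues the median was 0.116 for the same diet and number and -0.0758 for other numbers of the diet, with 6 of 12 pairs over 0.1 and all 12 above 0 (lowest 0.00357), a hint of pairing from the data and not the design. The number as a replicate block gave 4, 1495, 0, 28, 348 and 0 in liver, 0, 1, 1, 2, 58 and 1 in muscle and 386 for the difference between tissues. For the difference between tissues 159 of the 386 genes were among the 252.

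Leaving out 1 array at a time, which leaves 2 in its group, changed the counts as follows, in the order of replicates 1, 2 and 3. Liver negative control against normal control gave 20, 0 and 0 without normal control and 0, 0 and 8 without negative control. Liver PHF against negative control gave 811, 369 and 778 without negative control and 1564, 1381 and 776 without PHF. Liver CCL against negative control gave 0, 0 and 5 without negative control and 0, 255 and 16 without CCL. Liver PHF against CCL gave 38, 71 and 82 without PHF and 24, 16 and 132 without CCL. Liver PHF against normal control gave 251, 82 and 33 without normal control and 337, 327 and 188 without PHF. Liver CCL against normal control gave 1, 0 and 0 without normal control and 22, 0 and 0 without CCL. Muscle negative control against normal control gave 0, 1 and 16 without normal control and 1, 2 and 22 without negative control. Muscle PHF against negative control gave 1, 2 and 16 without negative control and 1, 1 and 4 without PHF. Muscle CCL against negative control gave 1, 2 and 19 without negative control and 3, 920 and 1 without CCL. Muscle PHF against CCL gave 1, 1 and 20 without PHF and 16, 1139 and 1 without CCL. Muscle PHF against normal control gave 15, 3 and 73 without normal control and 7, 4 and 366 without PHF. Muscle CCL against normal control gave 1, 1 and 3 without normal control and 3, 1 and 2 without CCL. The difference between tissues gave 89, 34 and 134 without liver negative control, 361, 295 and 82 without liver PHF, 61, 47 and 331 without muscle negative control, 74, 273 and 427 without muscle PHF.

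Normexp correction reversed the sign of GALR1L (0.11 from -1.04), CHDH (0.00275 from -0.26) and MAT1A (-0.0313 from 0.0154) in liver negative control against normal control and IL22 (-0.0913 from 2.08), PLIN3 (-0.00872 from 2.02), CD40 (-0.0437 from 0.84) and MAT1A (0.0275 from -0.0343) in liver PHF against negative control. IL22 (-0.0101 from 2.06) in liver CCL against negative control and CXCR1 (-0.11 from 2.34) and BPIFB3 (-0.20 from 2.15) in muscle negative control against normal control reversed. CXCR4 (-0.24 from 1.25) and BHMT (-0.0302 from 0.0291) in muscle PHF against negative control and SYT16 (-0.23 from 1.73) in muscle PHF against CCL reversed. POMP (-0.23 from 3.34), STEAP4 (-0.32 from 3.68), CXCR1 (-0.44 from 2.81), TSSK6 (-0.61 from 2.97), TLR5 (-0.72 from 1.32) and APOH (-0.15 from 1.83) in muscle PHF against normal control and CXCR1 (-0.21 from 1.59) in muscle CCL against normal control reversed. The mean of a gene's probes reversed the sign of PEMT (-0.0117 from 0.26) in liver PHF against negative control. The deposited table reversed the sign of NFIX (0.28 from -0.98) in liver negative control against normal control and PEMT (-0.00534 from 0.26) in liver PHF against negative control. SLC6A9 (0.78 from -3.04) in liver CCL against negative control and ATP5C1 (0.47 from -0.38) in muscle CCL against negative control reversed. SLCO1B1 (-0.15 from 1.55) in muscle PHF against CCL and IRF8 (-0.12 from 1.23) in muscle PHF against normal control reversed. LRRC73 (-0.44 from 0.99) and TIMD4 (-0.55 from 1.20) in muscle CCL against normal control reversed. Slide as a fixed block reversed the sign of BHMT (-0.36 from 0.24) and MAT1A (-0.17 from 0.0154) in liver negative control against normal control and CACNG7 (-0.0427 from 2.98) in liver PHF against negative control. BHMT (-0.00815 from 0.0291) in muscle PHF against negative control reversed. Slide as a fixed block reversed the mean of fatty acid and triglyceride synthesis (0.10 from -0.0734) and oxidative phosphorylation (0.0129 from -0.0554) in liver CCL against normal control, ribosomal proteins (0.0276 from -0.0725) in muscle negative control against normal control and fast muscle contraction (0.15 from -0.18) in muscle PHF against normal control. Leaving 1 array out reversed the sign of MAT1A (-0.0618 to 0.0986, -0.0618 without normal control 2, -0.016 without negative control 2 and -0.0364 without negative control 3 from 0.0154) in liver negative control against normal control and PCYT1A (-0.10 to 0.0247, 0.0218 without negative control 1 and 0.0247 without CCL 2 from -0.0289) and BHMT (-0.40 to 0.11, 0.0815 without negative control 3 and 0.11 without CCL 1 from -0.14) in liver CCL against negative control. MAT1A (-0.19 to 0.0808, 0.0174 without negative control 3, 0.0808 without PHF 2 and 0.00567 without PHF 3 from -0.0343) in liver PHF against negative control and BHMT (-0.0244 to 0.10, -0.00389 without negative control 2 and -0.0244 without PHF 1 from 0.0291) in muscle PHF against negative control reversed. Quantile normalization reversed the mean of fast muscle contraction (0.0446 from -0.0986) and ribosomal proteins (0.0306 from -0.10) in muscle PHF against negative control and ribosomal proteins (-0.13 from 0.14) in the difference between tissues. None of the signs reversed with 1 array left out belonged to a gene past the threshold.

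Among the named log2 changes past the threshold, 123 of 137 kept sign and side of the threshold with quantile normalization, 132 of 137 with the percentile over detected probes, 134 of 137 with outlier spots kept and 88 of 89 on features above background on every array. The number was 47 of 137 with normexp correction, 86 of 137 without a filter, 96 of 136 with the deposited table, 76 of 137 with a replicate block and 5 of 119 with slide as a fixed block. Gene list calls numbered 104 with the preset correlation, 82 after quantile normalization, 92 with slide as a block, 100 with the replicate block and 0 by camera with the correlation estimated. Of the 98 list calls within a tissue, slide as a block kept 45, weakened 49 and reversed 4. Signal over background limits what dim genes can show: a gene below background in a group has a lower bound in place of a fold, and 12 of the 20 signs that normexp correction reversed belonged to genes below background on all 3 arrays of a group compared. Of 221 named log2 changes, 124 were of genes with several probes, all of 1 sign for 112 of them, and TUBAL3 in liver PHF against negative control had probes past the threshold in both directions.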

Other observations

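The tests in this part were chosen after seeing the result. In liver, 79 of the 86 genes that differed between CCL and the negative control also differed in the same direction between PHF and the negative control. Independent lists of these lengths would share 3.8 genes, and lists of the same lengths from simulated groups without change, set against the shared negative control, shared 50 (highest 60 of 50 simulations). The covariance of the log2 changes over all genes was 0.179, against 0.0531 (0.0479 to 0.0576) in the simulations. The 3 shared control arrays cannot be split, and the simulations held no slide shift, so part of the excess may come from the shared arrays and their slide, as for the 79 genes of the negative control whose covariance was -0.157.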
